A study of Mus musculus with 46 samples.

How the data were processed

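The bulk measurements were RNA-seq libraries from the intestine of male C57BL/6J mice given metformin or the structurally related imeglimin. Per the labels' protocols, one experiment used a single oral dose of 600 mg/kg with colon taken after 6 h, and the other used drinking water with 3 mg/mL of drug for 4 weeks, after which proximal, middle and distal small intestine and colon were taken. Per the labels, each of the 15 groups (5 sets of tissue, each with control, imeglimin and metformin) held 3 samples. RNA was purified with RNeasy columns and libraries were made with the TruSeq Stranded mRNA kit, which selects polyadenylated RNA. A further sample, from colon after 12 weeks, was measured with 10x Fixed RNA Profiling, a probe-based single-cell assay on formaldehyde-fixed cells, per the labels.

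The authors deposited whole-number read counts per gene in 5 tables of 45777 gene symbols, 1 table for each set of 9 libraries, and no column was left unused (0). The submitters' processing notes name FastQC, Trimmomatic, HISAT2 and StringTie for reads and the builds mm10 and GRCm39 without their roles, so coordinates are not printed. Whether strand was used in counting is not given in the sources used here, and genes that overlap or have near-identical copies, such as the immunoglobulin variable genes, the alpha-defensins and the carboxylesterases, are uncertain for that reason. Of the counts from 1 to 50, between 50.0% and 51.3% were even, which shows no sign of doubled counting. Of the symbols, 40686 matched a RefSeq table of the assembly GRCm38.p6, which was used for names only. In chronic colon 26 symbols had turned into dates and were kept as deposited, so those genes dropped out of joins between tables. The deposited total per library was 31606797 to 47324301 counts. Every pair of replicates differed by more than sampling noise, with a chi-square of 13.4 to 196 per gene, and each library was used as 1 sample. The labels do not say that replicates are separate animals, or whether the chronic segments came from the same mice, so p-values measure the spread between these samples.

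The single-cell counts were deposited as 3 matrices of molecule (UMI) counts named CT, Ime and Met, written by Cell Ranger 9.0.0 per the file headers. All 3 belong to 1 GEO sample whose label lists every treatment, so the link of a matrix to a treatment rests on its deposited name alone and no test was run on these cells.

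Gene counts were tested with the edgeR 4.0.16 quasi-likelihood F test in R 4.3.3, with TMM scaling, genes kept by filterByExpr, a single fit of the 9 libraries of a table, and Benjamini-Hochberg adjustment over all genes tested, called at 0.05. Such p-values are written below as edgeR adjusted p. Levels are CPM, counts scaled by the library total and TMM factor, as mean ± SD of 3 libraries, and log2 fold changes are given ± SE. Between 17295 and 18665 genes were tested per table. Genes named in the text followed a rule set before the data were examined, as were 46 gene lists, the tests and the other settings to be tried. Genes past the threshold with a mean of at least 5 CPM in one of the groups, with group values that did not overlap and with no predicted-model symbol, were ranked by fold change. The 8 largest rises and falls per drug, the 2 smallest p per list, the 5 largest each way and 1 per list for imeglimin against metformin, the 5 smallest p per interaction, the 5 smallest p where fewer than 5 genes passed, and a fixed set (among them Gcg, Gdf15, Hk2, Slc2a1, Slc2a2, Slc5a1, Slc22a3, Slc29a4, Trib3 and Txnip) were taken. The text gives a part of them, and some genes are not reported here. Lists were tested with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison. The estimated correlation ended 257 of the 687 list results, and its p is given beside the list results from all libraries. Differences in a drug's effect between the 4 chronic segments (36 libraries, 20053 genes) and between acute and chronic colon (18 libraries, 19369 genes) were tested as interaction terms over tables that were counted separately.

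The labels give each library a batch tag equal to its replicate number, so by this tag the numbers pair the libraries. The mean correlation of the deviations of same-numbered libraries from their group means was -0.000326 in acute colon, 0.00559 in proximal, -0.0958 in middle and -0.126 in distal small intestine. In chronic colon it was 0.0808, against -0.0405 for pairs of other numbers. Of the 9 same-numbered pairs, 1 lay over 0.1 in acute colon, 0 in proximal, 2 in middle and 3 in distal small intestine and 3 in chronic colon. A fit with the batch as a block was run beside each result. The other settings chosen in advance were RLE scaling in place of TMM, the DESeq2 1.42.0 test and no filter beyond 1 read. Further ones were only the 2 groups compared, and leaving out each library in turn. For the interactions each replicate number was left out of every group at once. Covariates for smooth muscle and for B and plasma cell marker scores, the exclusion of a pair of libraries in middle small intestine, a single-cell doublet score limit, the list tests without each library in turn and a list of lysosomal genes were added after the data were seen.

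TMM assumes that most genes did not change. Without any scaling, the median log2 fold change of all genes would be -0.192 in place of -0.0475 for metformin in chronic colon, -0.119 in place of -0.0175 for imeglimin there, -0.164 in place of -0.0285 for metformin in distal small intestine, -0.144 in place of -0.0174 for imeglimin in middle small intestine and -0.14 in place of -0.0303 for imeglimin in acute colon, and changes are reported relative to the TMM scale.

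The edgeR steps were tested on simulated counts drawn from each table with 200 genes changed. In the simulated comparison of metformin with control, changes of 1 and 2 log2 units were recovered for 66% and 93% of genes in acute colon (18010 genes), 72% and 90% in proximal (17013), 50% and 86% in middle (17608) and 26% and 78% in distal small intestine (17908), and 52% and 88% in chronic colon (18329), with 3 to 6 false calls. For the difference of acute and chronic colon the shares were 35% and 75% (19038 genes), with 8 false calls.

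Cells with at least 200 detected genes were kept, scaled to 10000 counts, and clustered with scanpy 1.11.5 on 2000 variable genes, 30 principal components, 15 neighbours and Leiden at 1.0. A cluster was named only with at least 3 markers of a class detected in 5% of its cells and leading genes that did not go against the name. The last condition was extended after the clusters were seen, which left a cluster of 69 cells led by pancreatic genes unnamed. Scrublet set its threshold at 0.507 to 0.536, above the highest scores of 0.397 to 0.467, and so marked 0 doublets in every matrix. The caller did not work and doublets were left in. Shares carry exact (Clopper-Pearson) 95% binomial intervals and summed UMIs exact Poisson intervals, which cover counting error only.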

Results

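Gene expression was measured in 45 bulk RNA-seq libraries of mouse intestine, in 15 groups of 3. Colon was taken 6 h after an oral dose of metformin or imeglimin and from controls (acute), and proximal, middle and distal small intestine and colon were taken after 4 weeks of drug in the drinking water (chronic). The comparisons address where the drugs act alike in the intestine and where not. Metformin is a biguanide used in type 2 diabetes, and imeglimin is a structurally related tetrahydrotriazine. Single-cell counts of colon after 12 weeks came as 3 matrices without replicates. Every gene named below as changed between groups of 3 had all 3 libraries of 1 group beyond all 3 of the other, except Slc5a1 in acute colon. The edgeR adjusted p is from the quasi-likelihood test with Benjamini-Hochberg adjustment.

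**Figure D1:**
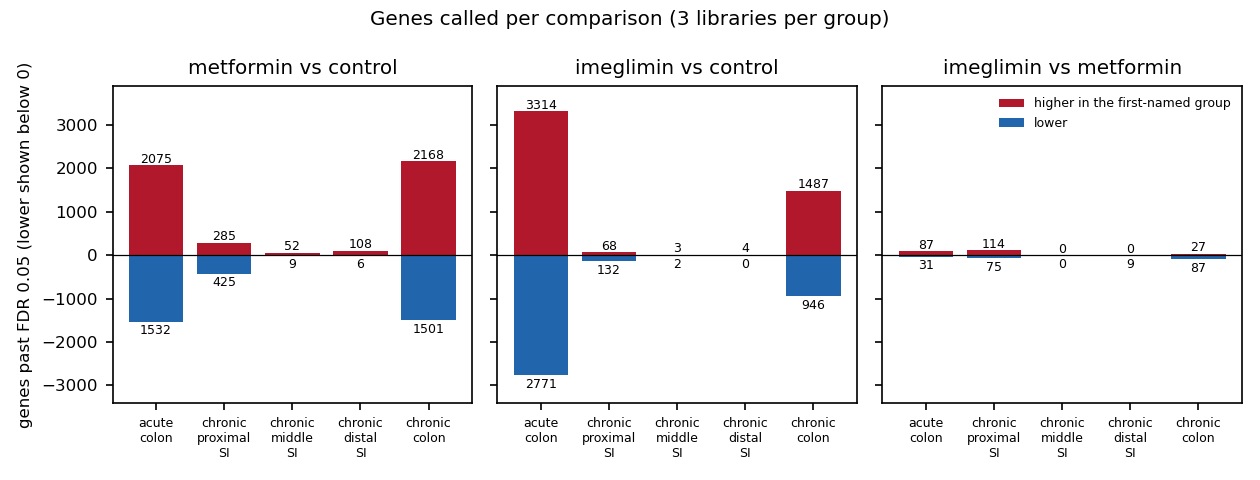
Bars give the number of genes past an edgeR adjusted p of 0.05 (y axis), higher above 0 and lower below 0, in the 5 sets of tissue (x axis) for each pair of groups of 3 libraries. The drug comparisons with control in acute and chronic colon have between 2433 and 6085 genes, and no comparison in small intestine has more than 710.

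At 6 h after metformin, colon showed a rise of genes of the integrated stress response, the program of the transcription factor ATF4. Chac1, which degrades glutathione, went from 0.944 ± 0.225 to 31.6 ± 5.63 CPM (SD, n = 3), a log2 fold change of 5.06 ± 0.28 (SE, edgeR adjusted p = 9.18e-06). Gdf15, a stress-induced hormone that lowers food intake, went from 0.831 ± 0.319 to 21.1 ± 6.02 CPM (4.67 ± 0.31, edgeR adjusted p = 1.71e-05). Areg, a ligand of the EGF receptor, went from 4.10 ± 1.51 to 75.1 ± 15.1 CPM (4.18 ± 0.26, edgeR adjusted p = 1.19e-05). Of 29 measured members of the stress response list 20 rose and 0 fell (23 adjusted over the list alone), with a median of 1.34 (camera adjusted p = 9.63e-35, and adjusted p = 0.345 with an estimated correlation). Among them were Trib3 (3.81 ± 0.48), Slc7a11, the cystine transporter (3.37 ± 0.34), and Mthfd2, a mitochondrial folate enzyme (2.94 ± 0.24), with edgeR adjusted p of 0.000474, 0.000146 and 6.23e-05.

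Hk2, Slc2a1 and Slc2a5, which handle hexoses, also changed in acute colon after metformin. Hexokinase 2 (Hk2) rose from 89.4 ± 7.89 to 260 ± 42.2 CPM (1.54 ± 0.15, edgeR adjusted p = 0.000122) and the glucose transporter Slc2a1 by 0.99 ± 0.15 (edgeR adjusted p = 0.00147). The fructose transporter Slc2a5 fell by 1.48 ± 0.20 (edgeR adjusted p = 0.000706). The intestinal sodium-glucose transporter Slc5a1 had a log2 fold change of -0.50 ± 0.16 (edgeR adjusted p = 0.0484, lower in 2 of 3 libraries). It missed the threshold without control 1 (0.155), control 2 (0.102), metformin 1 (0.131) or metformin 3 (0.0974) and with the replicate block (0.0708), no filter (0.0555) or only the 2 groups compared (0.0885). Proglucagon (Gcg) stood at 0.19 ± 0.15 (edgeR adjusted p = 0.4). Heat shock genes rose in 14 of 18 members (14 adjusted over the list alone, median 0.73, camera adjusted p = 5.19e-14, and adjusted p = 0.38 with an estimated correlation), such as Hsp90aa1 (1.13 ± 0.12, edgeR adjusted p = 0.000214). Of 36 nuclear-encoded genes of respiratory complex I, 13 rose (19 adjusted over the list alone). Their median was 0.29 (camera adjusted p = 3.29e-06, and adjusted p = 0.748 with an estimated correlation). Among the 8 largest falls was that of Lrat, which esterifies retinol, from 20.9 to 2.75 CPM (-2.93 ± 0.22, edgeR adjusted p = 4.37e-05). Of 39 interferon-induced genes 8 fell and 3 rose (10 and 3 adjusted over the list alone), with Ifit1bl1 at -2.21 ± 0.21 (edgeR adjusted p = 0.000122). The list median was -0.36 (camera adjusted p = 0.022, and adjusted p = 0.75 with an estimated correlation). Its camera adjusted p was 0.322 without control 2, where the median was -0.11, 0.0636 without metformin 1 and 0.0587 without metformin 3. In all, 3607 of 18294 genes passed the threshold, 2075 higher and 1532 lower, and 2169 did without control 3. Smooth muscle markers had a median of -0.355 with 0 of 19 called by edgeR in this comparison (camera adjusted p = 0.0323, and adjusted p = 0.833 with an estimated correlation). This rested on metformin 2, in which their mean log2 CPM was 5.85 against 7.75 and 7.23 in metformin 1 and 3. Without metformin 2 the median was -0.00051 (camera adjusted p = 0.758), without metformin 1 it was -0.88, and without control 3 the camera adjusted p was 0.0792. Paneth cell markers fell in 4 of 6 members (4 adjusted over the list alone, median -2.36, camera adjusted p = 0.0868, and adjusted p = 0.748 with an estimated correlation). Their mean log2 CPM was 2.02 in control 1 against -0.0629 and 0.11 in the other controls, and without control 1 the median was -1.27 with 0 called. The camera adjusted p was under 0.05 without control 2 (0.000629, median -4.2), control 3 (0.025), metformin 1 (0.0427) or metformin 2 (0.0439, median -3.67). Markers of enteric neurons and glia fell in 1 of 17 (1 adjusted over the list alone). Their median was -0.495 (camera adjusted p = 0.0172, and adjusted p = 0.748 with an estimated correlation), without metformin 1 it was -0.819 and without metformin 2 it was -0.137 (camera adjusted p = 0.295).

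With imeglimin in acute colon, Gdf15, Areg and Chac1 were again among the 8 largest rises. Gdf15 rose to 86.1 ± 18.1 CPM (6.69 ± 0.32, edgeR adjusted p = 2.18e-06) and Areg to 190 ± 37.4 CPM (5.52 ± 0.27, edgeR adjusted p = 2.36e-06). Chac1 rose to 42.5 ± 12.7 CPM (5.48 ± 0.29, edgeR adjusted p = 2.55e-06). The stress response list had 23 members higher and 1 lower (25 and 1 adjusted over the list alone). Their median was 1.48 (camera adjusted p = 9.22e-29, and adjusted p = 0.328 with an estimated correlation). Heat shock genes rose in 14 of 18 members (14 adjusted over the list alone). Their median was 1.09 (camera adjusted p = 2.06e-23, and adjusted p = 0.246 with an estimated correlation). Hspa8, the constitutive member of this chaperone family, went from 1005 to 2765 CPM (1.46 ± 0.11, edgeR adjusted p = 1.54e-05). Immediate early genes rose in 17 of 27 members (17 adjusted over the list alone). Their median was 0.84 (camera adjusted p = 2.07e-10, and adjusted p = 0.335 with an estimated correlation). Nuclear-encoded complex I genes rose in 32 of 36 (34 adjusted over the list alone), for instance Ndufb10 (0.86 ± 0.12, edgeR adjusted p = 0.000502). Their median was 0.55 (camera adjusted p = 6.03e-11, and adjusted p = 0.823 with an estimated correlation). ND5, encoded by the mitochondrial genome, fell from 4430 to 1828 CPM (-1.28 ± 0.14, edgeR adjusted p = 0.00014). Hk2 rose by 1.88 ± 0.15 and Slc2a1 by 0.86 ± 0.15, and Txnip, an inhibitor of glucose uptake, fell by 1.29 ± 0.16, with edgeR adjusted p of 1.9e-05, 0.0017 and 0.00028. Interferon-induced genes fell in 20 of 39 members and rose in 2 (23 and 3 adjusted over the list alone). Their median was -0.64, and -0.42 without control 2 (camera adjusted p = 6.01e-05, and adjusted p = 0.776 with an estimated correlation). Cell-type markers moved too, with no camera call. Endothelial markers fell in 7 of 17 members (7 adjusted over the list alone, and 4 called without control 1), with a median of -0.285 (camera adjusted p = 0.162, and adjusted p = 0.936 with an estimated correlation). Fibroblast markers fell in 3 of 20 (1 adjusted over the list alone, and 1 or 2 called without any 1 library). Their median was -0.309 (camera adjusted p = 0.0899, and adjusted p = 0.969 with an estimated correlation), with a camera adjusted p of 0.0329 without control 1 and 0.043 without imeglimin 1. Paneth cell markers fell in 4 of 6 (4 adjusted over the list alone, median -2.7, camera adjusted p = 0.162, and adjusted p = 0.969 with an estimated correlation). Without control 1 their median was -1.52 with 2 called, without control 2 it was -4.81 (camera adjusted p = 0.00349), and without imeglimin 1 or 3 it was -4.43 and -4.63. Goblet cell markers rose in 3 of 16 (3 adjusted over the list alone, and 1 to 4 called without 1 library, median 0.142, camera adjusted p = 0.276, and adjusted p = 0.969 with an estimated correlation). In number 6085 genes passed, 3314 higher and 2771 lower, and 4004 did without imeglimin 2.

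Between the drugs at the same acute dose, 118 genes differed (87 higher and 31 lower with imeglimin), with 3009 at an unadjusted p under 0.05 and 733 by DESeq2. Gdf15 was higher with imeglimin by 2.03 ± 0.23 (95% interval 1.51 to 2.54, edgeR adjusted p = 0.00979), and Mx1, an interferon-induced GTPase, by 1.47 ± 0.16 (edgeR adjusted p = 0.0097). Without imeglimin 2 each had an adjusted p of 0.0537. Chac1 differed by 0.43 (95% interval -0.043 to 0.90, edgeR adjusted p = 0.346) and Hk2 by 0.34 (0.029 to 0.65, edgeR adjusted p = 0.268). Slc2a1 differed by -0.13 (-0.46 to 0.21, edgeR adjusted p = 0.712) and Gcg by 0.14 (-0.19 to 0.47). None of these 4 passed the threshold. The median half-width of the intervals was 0.36, and 74.4% of genes had an interval within 1 log2 unit of 0 on either side. Immediate early genes had 2 members higher (12 adjusted over the list alone, median 0.44, camera adjusted p = 1.92e-11, and adjusted p = 0.231 with an estimated correlation). Cholesterol synthesis genes had 0 called by edgeR over all genes (13 lower adjusted over the list alone). Their median was -0.36, and -0.21 without metformin 1 (camera adjusted p = 5.13e-09, and adjusted p = 0.568 with an estimated correlation). Smooth muscle markers had a median of 0.30, with 0 called by edgeR (camera adjusted p = 0.0147, and adjusted p = 0.806 with an estimated correlation). Without metformin 2 their median was -0.04 (camera adjusted p = 0.367), without imeglimin 1 it was 0.155 (camera adjusted p = 0.378), and without metformin 1 it was 0.80. The count fell to 11 without imeglimin 1, 0 without imeglimin 2, 9 without imeglimin 3 and 11 without metformin 3, and to 19 with the replicate block.

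**Figure D2:**
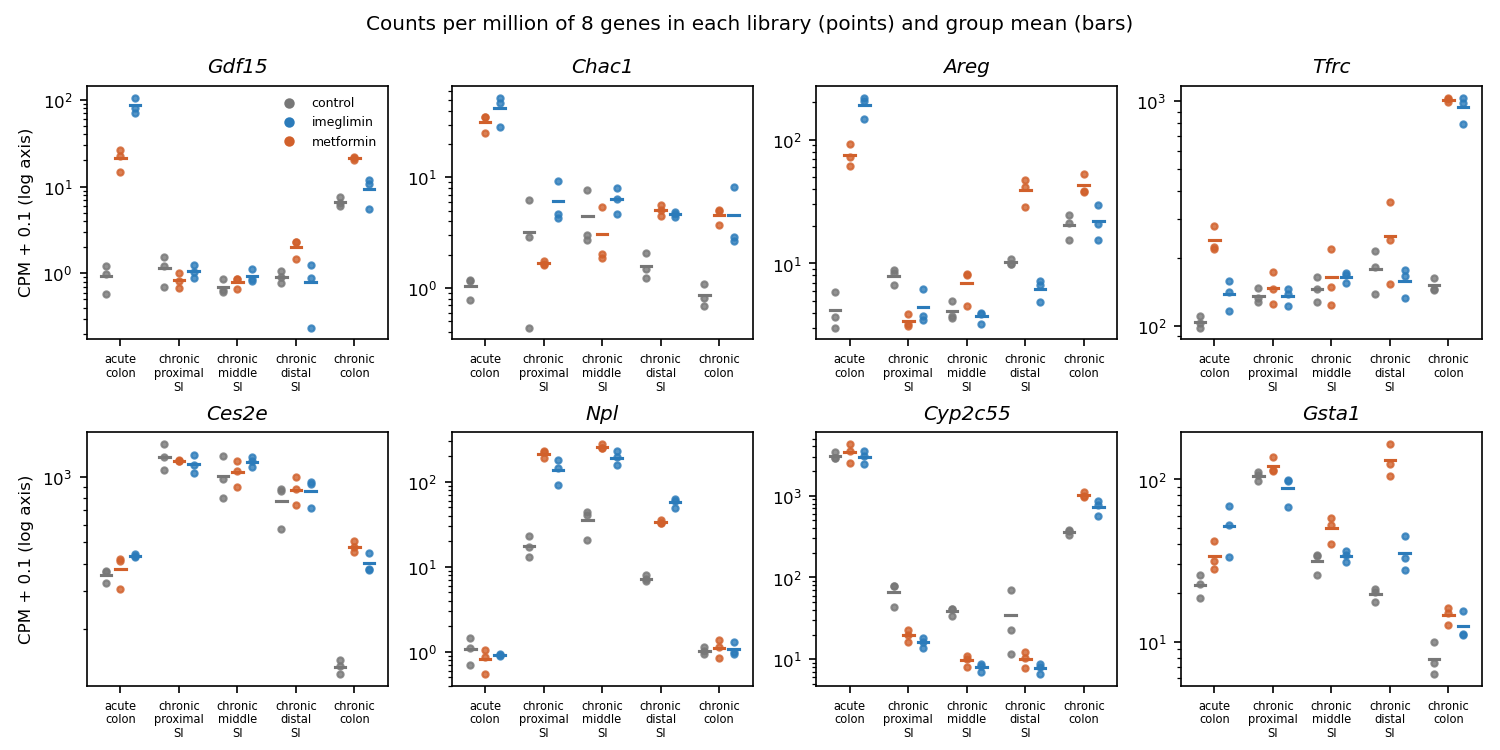
Points give CPM plus 0.1 on a log axis for each of the 3 libraries per group, and bars the group means, of Gdf15, Chac1, Areg, Tfrc, Ces2e, Npl, Cyp2c55 and Gsta1 in the 5 sets of tissue. Gdf15 stood at 86.1 CPM after imeglimin and 21.1 after metformin in acute colon against 0.831 in control, and Tfrc at 1019 CPM after metformin in chronic colon against 151 in control.

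After 4 weeks, the colon of metformin-treated mice showed higher transferrin receptor, the cellular importer of iron, and higher genes of the respiratory chain. Tfrc rose from 151 ± 10.9 to 1019 ± 22 CPM (2.76 ± 0.11, edgeR adjusted p = 2.8e-06). All 36 nuclear-encoded complex I genes rose (36 adjusted over the list alone). Their median was 0.75 (camera adjusted p = 4.28e-46, and adjusted p = 0.133 with an estimated correlation). All 35 genes of complexes II to V rose as well (35 adjusted over the list alone, median 0.705, camera adjusted p = 3.13e-46, and adjusted p = 0.132 with an estimated correlation). Among them was Uqcrq (1.45 ± 0.095, edgeR adjusted p = 7.17e-05). The carboxylesterase Ces2e rose from 135 ± 9.95 to 478 ± 28.9 CPM (1.83 ± 0.095, edgeR adjusted p = 2.95e-05). The cytochrome P450 Cyp2c55 rose by 1.5 ± 0.14 (edgeR adjusted p = 0.000239). Stress response genes rose in 15 of 29 members (18 and 1 lower adjusted over the list alone, median 0.57, camera adjusted p = 3.72e-14, and adjusted p = 0.0849 with an estimated correlation). Mthfd2 stood at 2.97 ± 0.27, Atf5 at 2.34 ± 0.17 and Gdf15 at 1.68 ± 0.24 (edgeR adjusted p = 0.000239, 7.62e-05 and 0.00159). Of 18 metal-handling genes 8 rose and 1 fell (8 and 2 adjusted over the list alone, median 0.28, camera adjusted p = 4.8e-09, and adjusted p = 0.0266 with an estimated correlation).

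Slc37a2, Slc34a2 and Trpv6 were among the 8 largest falls with metformin in chronic colon. Slc37a2 fell from 464 to 46.3 CPM (-3.33 ± 0.33, edgeR adjusted p = 0.000291) and the phosphate transporter Slc34a2 from 42.3 to 5.36 CPM (-2.98 ± 0.31, edgeR adjusted p = 0.00035). The calcium channel Trpv6 fell from 9.86 to 0.707 CPM (-3.8 ± 0.26, edgeR adjusted p = 7.17e-05). Slc2a1 rose by 0.82 ± 0.079 (edgeR adjusted p = 0.000291), while Hk2 stood at 0.14 (edgeR adjusted p = 0.45). Gcg was lower by a log2 fold change of -0.77 ± 0.19 (edgeR adjusted p = 0.0205), which missed the threshold without control 1 (0.0676), control 2 (0.0572), metformin 2 (0.0837) or metformin 3 (0.0596). Smooth muscle markers fell in 12 of 19 members (14 adjusted over the list alone, median -0.42, camera adjusted p = 1.28e-06, and adjusted p = 0.53 with an estimated correlation). Fibroblast markers fell in 11 of 20 with 1 higher (13 and 1 adjusted over the list alone). Their median was -0.39 (camera adjusted p = 0.000597, and adjusted p = 0.568 with an estimated correlation). B and plasma cell markers had 0 of 19 called (0 adjusted over the list alone) and a median of -1.33 (camera adjusted p = 0.00212, and adjusted p = 0.628 with an estimated correlation). Their mean log2 CPM was 1.97 and 1.56 in metformin 2 and 3, against 4.11 in metformin 1 and 4.13 to 4.39 in the controls. Without metformin 1 their median was -2.84 with 15 called lower, and without metformin 2 or 3 it was -0.876 and -0.855. T and NK cell markers had 1 of 19 lower (0 adjusted over the list alone) and a median of -0.795 (camera adjusted p = 0.0174, and adjusted p = 0.66 with an estimated correlation). Without metformin 2 or 3 their camera adjusted p was 0.0723 and 0.0914, and without metformin 1 their median was -1.25 with 9 called lower. Goblet cell markers rose in 4 of 16 members (5 adjusted over the list alone, median 0.162, camera adjusted p = 0.012, and adjusted p = 0.628 with an estimated correlation). Their median was 0.294 without control 2, 0.27 without metformin 3 and 0.0595 without metformin 1 (camera adjusted p = 0.0832). Control 3 carried pancreatic transcripts, with the carboxypeptidase gene Cpb1 at 1940 CPM against at most 0.565 in the other libraries. Of 18665 genes 3669 passed (2168 higher and 1501 lower). The count was 2358 without control 1, 2106 without control 3 and 2066 without metformin 2. With the smooth muscle marker score as a covariate, chosen after the data were seen, 111 genes passed and 49 of the 69 genes taken by the naming rule missed the threshold, and with the B and plasma cell score 658 passed and 31 of the 69 missed it.

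With imeglimin in chronic colon, Tfrc rose to 940 ± 127 CPM (2.64 ± 0.11, edgeR adjusted p = 4.09e-06) and Ces2e to 400 ± 41.7 CPM (1.57 ± 0.095, edgeR adjusted p = 0.00012). The hexokinase homologue Hkdc1 rose from 4.95 ± 0.545 to 43.4 ± 20 CPM (3.14 ± 0.30, edgeR adjusted p = 0.00233). Genes of cholesterol synthesis rose in 19 of 26 members (24 adjusted over the list alone, median 0.90, camera adjusted p = 1.35e-18, and adjusted p = 0.237 with an estimated correlation). Among them was Hmgcs1, a synthase early in the pathway, at 1.31 ± 0.20 (edgeR adjusted p = 0.00534). Complex I genes rose in 31 of 36, mitochondrially encoded genes in 11 of 13 and glycolysis genes in 14 of 24. Adjusted over the list alone these were 33, 12, and 15 with 1 lower. Their medians were 0.51, 0.39 and 0.38 (camera adjusted p = 1.11e-28, 3.95e-09 and 8.35e-09, and adjusted p = 0.237, 0.268 and 0.237 with an estimated correlation). Proliferation genes rose in 11 of 30 (17 adjusted over the list alone). Their median was 0.89, and 1.37 without control 2 (camera adjusted p = 1.53e-13, and adjusted p = 0.268 with an estimated correlation). Slc37a2 fell to 68.8 CPM (-2.75 ± 0.32, edgeR adjusted p = 0.00292). Slc2a1 rose by 0.46 ± 0.079 (edgeR adjusted p = 0.00717). Gdf15 stood at 0.51 ± 0.24 (edgeR adjusted p = 0.201, and 0.0129 without imeglimin 2) and Gcg at 0.004 ± 0.19 (edgeR adjusted p = 0.992). Smooth muscle markers had a median of -0.13 with 0 called (camera adjusted p = 0.101, and 0.00593 without imeglimin 2, and adjusted p = 0.882 with an estimated correlation). B and plasma cell markers had 1 of 19 higher (1 adjusted over the list alone) and a median of -0.88, and -0.486 without imeglimin 3 (camera adjusted p = 0.349, and adjusted p = 0.939 with an estimated correlation). Fibroblast markers fell in 3 of 20 with 1 higher (6 and 1 adjusted over the list alone, median -0.27, camera adjusted p = 0.00423, and adjusted p = 0.573 with an estimated correlation), with 0 lower without control 1 or imeglimin 3, 1 without imeglimin 1 and 5 without imeglimin 2. In number 2433 genes passed (1487 higher and 946 lower). The number was 1222 without control 1, 932 without control 3, 1546 without imeglimin 1, 1500 without imeglimin 2 and 1569 without imeglimin 3. With the smooth muscle score as a covariate the count was 1308, and with the B and plasma cell score 1301.

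Compared with each other in chronic colon, the drugs differed in 114 genes (27 higher and 87 lower with imeglimin), with 3523 at an unadjusted p under 0.05 and 1292 by DESeq2. Skeletal actin (Acta1) was lower with imeglimin, 8.36 against 87.6 CPM (-3.39 ± 0.22, 95% interval -3.89 to -2.89, edgeR adjusted p = 0.000572). The stress response factor Atf5 was lower too, 31.7 against 97.3 CPM (-1.62 ± 0.16, -1.98 to -1.25, edgeR adjusted p = 0.0074). Slc34a2 was higher with imeglimin, 46.4 against 5.36 CPM (3.11 ± 0.31, 2.42 to 3.8, edgeR adjusted p = 0.0074). Stress response genes were lower in 4 of 29 members (9 adjusted over the list alone, median -0.33, and -0.51 without imeglimin 3, camera adjusted p = 6.38e-13, and adjusted p = 0.0973 with an estimated correlation). Mitochondrially encoded genes were higher in 3 of 13 (10 adjusted over the list alone). Their median was 0.33 (camera adjusted p = 2.07e-08, and adjusted p = 0.556 with an estimated correlation). Not past the threshold were Tfrc at -0.12 (95% interval -0.34 to 0.10, edgeR adjusted p = 0.565) and Ces2e at -0.26 (-0.46 to -0.051, edgeR adjusted p = 0.18). Nor did Gdf15 pass, at -1.17 (-1.7 to -0.64, edgeR adjusted p = 0.0602), or Gcg at 0.78 (0.35 to 1.21, edgeR adjusted p = 0.0903) or Slc2a1 at -0.36 (-0.54 to -0.19, edgeR adjusted p = 0.0694). These 3 passed without imeglimin 3 (0.0276, 0.0151 and 0.0449) and by DESeq2 (adjusted p = 0.000103, 0.0021 and 0.00119). Smooth muscle markers had a median of 0.315 with 0 called (6 adjusted over the list alone, camera adjusted p = 5.62e-07, and adjusted p = 0.556 with an estimated correlation), and with that score as a covariate 0 genes passed. Without imeglimin 2 or 3 the median was 0.177 and 0.206. B and plasma cell markers had 0 called and a median of 0.52 (camera adjusted p = 0.000474, and adjusted p = 0.59 with an estimated correlation). Their camera adjusted p was 0.0547 without metformin 3, and their median ranged from 0.148 without metformin 2 to 1.92 without metformin 1. With that score as a covariate 5 genes passed. The count was 62 without imeglimin 1, 16 without imeglimin 2, 543 without imeglimin 3, 32 without metformin 1, 18 without metformin 2 and 11 without metformin 3.

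**Figure D3:**
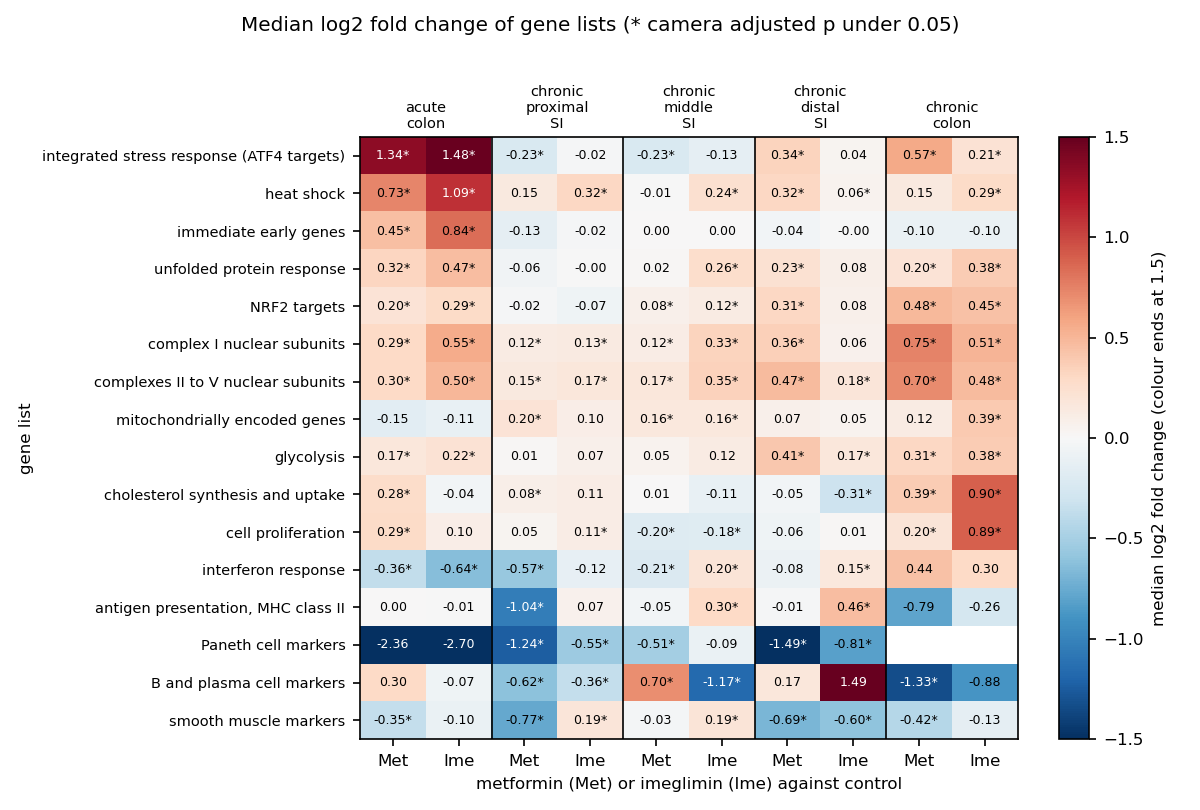
The heat map gives the median log2 fold change of 16 gene lists (y axis) for metformin (Met) and imeglimin (Ime) against control in the 5 sets of tissue (x axis), with colour ending at 1.5, a star where the camera adjusted p at the preset correlation is under 0.05, and blanks where fewer than 5 members were tested. The star on the B and plasma cell list for metformin in middle small intestine stands on a median of 0.70 and a test in the lower direction.

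In proximal small intestine the sialic acid lyase Npl, which breaks down N-acetylneuraminate, rose with both drugs. From 17.7 ± 4.97 CPM it went to 215 ± 21.3 with metformin (3.60 ± 0.25, edgeR adjusted p = 0.00025) and 139 ± 44.8 with imeglimin (2.97 ± 0.25, edgeR adjusted p = 0.00153). Cyp2c55 fell from 67.0 ± 19.9 CPM to 19.5 ± 3.37 (-1.78 ± 0.21, edgeR adjusted p = 0.00742) and 16.1 ± 2.29 (-2.06 ± 0.21, edgeR adjusted p = 0.00445). With metformin Acadl, an enzyme of fatty acid oxidation, rose by 0.49 ± 0.061, and Slc51b, part of the basolateral bile acid exporter, fell by 0.67 ± 0.080 (both edgeR adjusted p = 0.00753). With imeglimin the glutathione transferase Gstm3 fell from 248 to 88.1 CPM (-1.49 ± 0.19, edgeR adjusted p = 0.0103) and the manganese exporter Slc30a10 from 44.3 to 26.7 CPM (-0.73 ± 0.090, edgeR adjusted p = 0.00956).

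Cell-type markers moved in the same metformin libraries of proximal small intestine. Paneth cell markers fell in 13 of 15 members and smooth muscle markers in 15 of 19 (15 and 19 adjusted over the list alone). Their medians were -1.24 and -0.77 (camera adjusted p = 2.58e-33 and 1.51e-29, and adjusted p = 0.151 for both with an estimated correlation). B and plasma cell markers fell in 4 of 18 (11 adjusted over the list alone). Their median was -0.62 (camera adjusted p = 4.31e-08, and adjusted p = 0.0491 with an estimated correlation). T and NK cell markers fell in 5 of 19 and myeloid cell markers in 5 of 21 (13 and 10 adjusted over the list alone). Their medians were -0.46 and -0.65 (camera adjusted p = 3.06e-09 and 1.33e-09, and adjusted p = 0.22 and 0.151 with an estimated correlation). Fibroblast markers fell in 6 of 20 (13 adjusted over the list alone, median -0.51, camera adjusted p = 9.39e-09, and adjusted p = 0.22 with an estimated correlation). Of 17295 genes 710 passed with metformin (285 higher and 425 lower), and 470 with the replicate block. There were 274 without control 1, 441 without control 3, 154 without metformin 1, 338 without metformin 2, 52 without metformin 3, 4 with the smooth muscle score as a covariate and 0 with the B and plasma cell score, so that all 39 genes taken by the naming rule missed the threshold with either score.

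With imeglimin in proximal small intestine, endothelial markers fell in 2 of 17 members and myeloid cell markers in 2 of 21 (13 and 9 adjusted over the list alone). Their medians were -0.60 and -0.55 (camera adjusted p = 3.62e-11 and 7.55e-08, and adjusted p = 0.189 for both with an estimated correlation). B and plasma cell markers had 0 of 18 called by edgeR (2 lower adjusted over the list alone, median -0.36, camera adjusted p = 3.02e-05, and adjusted p = 0.182 with an estimated correlation). Paneth cell markers had 0 of 15 called (9 lower adjusted over the list alone). Their median was -0.55, and -0.296 without control 3 (camera adjusted p = 6.45e-09, and adjusted p = 0.555 with an estimated correlation). Smooth muscle markers had 0 called and a median of 0.19 (camera adjusted p = 0.00398, and adjusted p = 0.753 with an estimated correlation), with a camera adjusted p of 0.147 without control 2 and 0.0552 without imeglimin 3. With imeglimin 200 genes passed (68 higher and 132 lower), 80 with the replicate block, 11 without control 1, 113 without control 2, 39 without imeglimin 1, 9 without imeglimin 2 and 35 without imeglimin 3. With the smooth muscle score as a covariate 43 passed and 18 of the 30 genes taken by the naming rule missed the threshold. With the B and plasma cell score 2 passed and all 30 missed it. The B and plasma cell score lay below all controls with imeglimin too, so it overlaps with the treatment. Between the drugs 189 differed, 94 with the replicate block, 43 without imeglimin 1, 111 without imeglimin 2, 45 without imeglimin 3, 0 without metformin 1, 0 without metformin 3, 2 with the smooth muscle score and 0 with the B and plasma cell score. Smooth muscle markers were higher with imeglimin in 16 of 19 members (19 adjusted over the list alone). Their median was 0.98 (camera adjusted p = 1.85e-55, and adjusted p = 0.139 with an estimated correlation). Npl differed by -0.63 (95% interval -1.12 to -0.14, edgeR adjusted p = 0.185), Cyp2c55 by -0.28 (-0.74 to 0.18, edgeR adjusted p = 0.535) and Slc5a1 by 0.03 (-0.22 to 0.28).

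Npl and Cyp2c55 moved in the same directions in middle small intestine. Cyp2c55 fell from 38.7 ± 4.49 to 9.57 ± 1.56 CPM with metformin (-2.02 ± 0.15, edgeR adjusted p = 0.00322) and to 7.93 CPM with imeglimin (-2.29 ± 0.15, edgeR adjusted p = 0.00117). Npl rose from 35.1 ± 12.4 to 260 ± 15.9 CPM with metformin (2.89 ± 0.26, edgeR adjusted p = 0.00561, and 0.0535 without control 2). With imeglimin it rose to 193 ± 35.6 CPM (2.46 ± 0.26, edgeR adjusted p = 0.015, and 0.109 without control 2, 0.0911 without imeglimin 2 and 0.105 without imeglimin 3). Complex I genes had 0 of 36 called with imeglimin over all genes (27 adjusted over the list alone). Their median was 0.33 (camera adjusted p = 1.13e-16, and adjusted p = 0.739 with an estimated correlation). The B and plasma cell list had a median of 0.70 with metformin and a camera test in the lower direction (adjusted p = 0.0257, and adjusted p = 0.758 with an estimated correlation). Its camera adjusted p was 0.55 without control 1, 0.25 without metformin 1 and 0.309 without metformin 2, and without metformin 3 its median was -2.31. With imeglimin its median was -1.17 (camera adjusted p = 0.0356, and adjusted p = 0.828 with an estimated correlation). Without control 1 it was 0.23 (camera adjusted p = 0.774), and without imeglimin 3 the camera adjusted p was 0.281. With imeglimin edgeR called 0 of 17 endothelial and 0 of 14 stem cell markers (10 and 5 lower adjusted over the list alone). Their medians were -0.559 and -0.347 (camera adjusted p = 1.4e-07 and 0.00422, and adjusted p = 0.208 and 0.739 with an estimated correlation). Metformin had 61 of 17940 genes past the threshold, 23 with the replicate block, 20 without control 1, 2 without control 2, 19 without metformin 1, 97 without metformin 2 and 21 without metformin 3. Imeglimin had 5, 3 without control 2, 8 without control 3, 1 without imeglimin 2 and 1 without imeglimin 3. Besides Npl and Cyp2c55 these were Pcf11 (-0.76 ± 0.067, edgeR adjusted p = 0.00696, and 0.091 without imeglimin 2 and 0.105 without imeglimin 3), Paqr8 and Igkv6-14. Paqr8 stood at 1.31 ± 0.16 (edgeR adjusted p = 0.0482) and missed the threshold without control 1 (0.145), control 2 (0.216), control 3 (0.0577), imeglimin 2 (0.182) or imeglimin 3 (0.233) and with only the 2 groups compared (0.0697). Igkv6-14, an immunoglobulin segment outside the naming rule that was picked after its values were seen, stood at 2.63 ± 0.27 (edgeR adjusted p = 0.015), and reads shared with related segments leave its count uncertain. Without control 1 and metformin 3, a pair chosen after the data were seen for their high B cell scores, the counts were 6 and 11. Between the drugs edgeR called 0 genes, with 2373 at an unadjusted p under 0.05, 312 by DESeq2 and 2 by edgeR without metformin 2, and Npl differed by -0.43 (95% interval -0.97 to 0.11, edgeR adjusted p = 0.463).

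In distal small intestine metformin raised the glutathione transferase Gsta1 from 19.6 ± 1.89 to 132 ± 30.5 CPM (2.75 ± 0.22, edgeR adjusted p = 0.00509). The phosphatase gene Dusp14 rose from 1.89 to 15.1 CPM (3.00 ± 0.27, edgeR adjusted p = 0.00509), and Ddit3, the stress-induced transcription factor CHOP, from 14.9 to 42.0 CPM (1.5 ± 0.15, edgeR adjusted p = 0.0062). Stress response genes rose in 5 members (11 adjusted over the list alone). Their median was 0.34 (camera adjusted p = 1.92e-11, and adjusted p = 0.059 with an estimated correlation). Npl rose from 7.17 ± 0.595 to 33.7 ± 1.47 CPM with metformin (2.23 ± 0.13, edgeR adjusted p = 0.00093) and to 57.2 ± 7.74 CPM with imeglimin (3.00 ± 0.13, edgeR adjusted p = 9.52e-05). Between the drugs it differed by 0.76 (edgeR adjusted p = 0.155), which did not pass. The metformin value of this gene lay outside the naming rule and was picked after it was seen. Between the drugs Areg was lower with imeglimin by a log2 difference of -2.67 ± 0.23 (95% interval -3.19 to -2.16, edgeR adjusted p = 0.00955, and 0.0661 without imeglimin 3, 0.0592 without metformin 3 and 0.0959 with only the 2 groups compared). Hk2 differed by -0.77 (-1.26 to -0.27, edgeR adjusted p = 0.427) and Slc2a1 by -0.98 (-1.41 to -0.55, edgeR adjusted p = 0.272, and 0.000578 by DESeq2). Stress response genes were lower with imeglimin in 2 members (9 adjusted over the list alone). Their median was -0.30 (camera adjusted p = 1.79e-13, and adjusted p = 0.0376 with an estimated correlation). Smooth muscle markers had a median of -0.69 with metformin (camera adjusted p = 3.66e-11, and adjusted p = 0.471 with an estimated correlation). With imeglimin the median was -0.60, and -0.365 without imeglimin 3 (camera adjusted p = 1.39e-10, and adjusted p = 0.556 with an estimated correlation), with 0 of 19 called by edgeR in either. Stem cell markers had 0 of 14 called in either (8 and 6 lower adjusted over the list alone). Their medians were -0.469 with metformin and -0.478 with imeglimin (camera adjusted p = 2.82e-06 and 1.52e-06, and adjusted p = 0.471 and 0.556 with an estimated correlation). Fibroblast markers had 0 of 20 called in either (0 and 0 adjusted over the list alone), with medians of -0.603 and -0.614, and -0.352 and -0.403 without control 1 (camera adjusted p = 2.14e-06 and 1.24e-09, and adjusted p = 0.471 and 0.556 with an estimated correlation). Metformin had 114 of 18233 genes past the threshold (108 higher and 6 lower), and 17 with the replicate block. It had 69 without control 1, 8 without control 2, 44 without control 3, 14 without metformin 2, 14 without metformin 3 and 1 with the smooth muscle score as a covariate. Imeglimin had 4, 1 with the replicate block, 1 without each of the controls in turn, 2 without imeglimin 1 or imeglimin 2, 1 without imeglimin 3 and 1 with the smooth muscle score. Besides Npl these were Ctsl, the lysosomal protease cathepsin L (0.90 ± 0.092), Gm5540 (1.70 ± 0.18) and Tnfrsf23 (2.25 ± 0.24), each with an edgeR adjusted p of 0.0356. All 4 were also called higher with metformin. All 3 missed the threshold with the replicate block (0.228), with only the 2 groups compared (0.14 to 0.199) and without any single control or imeglimin library, where their adjusted p lay between 0.0684 and 0.238. Between the drugs 9 genes differed, 3 with the replicate block, 3 without imeglimin 1, 2 without imeglimin 2, 0 without imeglimin 3, 1 without metformin 2 and 0 without metformin 3.

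For each cell-type marker list, mean log2 CPM was compared with control. Chance puts all 3 drug libraries beyond all 3 controls for 10% of lists. In acute colon Paneth cell, endothelial and neuron and glia markers lay below all controls with metformin and absorptive colonocyte and goblet cell markers above. With imeglimin Paneth cell, endothelial, fibroblast, tuft cell and liver markers lay below there and goblet cell and erythrocyte markers above. In proximal small intestine B and plasma cell, T and NK cell, myeloid cell and pancreatic markers lay below with both drugs, Paneth cell, smooth muscle, fibroblast and neuron and glia markers with metformin alone, and endothelial and erythrocyte markers with imeglimin alone. In middle small intestine stem cell and endothelial markers lay below with both drugs, neuron and glia and erythrocyte markers below and adipocyte markers above with metformin alone, and Paneth cell markers below and enteroendocrine markers above with imeglimin alone. In distal small intestine stem cell, fibroblast and neuron and glia markers lay below with both drugs, Paneth cell, smooth muscle, tuft cell and pancreatic markers with metformin alone, and liver markers with imeglimin alone. In chronic colon B and plasma cell markers lay below with both drugs, and smooth muscle and fibroblast markers below and goblet cell markers above with metformin alone. Whether these lists differed between the drugs was not tested on the means.

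In acute colon with metformin, absorptive colonocyte markers had 5 of 22 higher and 1 lower (5 and 1 adjusted over the list alone, median 0.15, camera adjusted p = 0.0577, and adjusted p = 0.41 with an estimated correlation). Their camera adjusted p was 0.0419 without control 1, 0.0329 without control 3 and 0.0439 without metformin 2. Goblet cell markers had 3 of 16 higher and endothelial markers 3 of 17 lower (3 and 4 adjusted over the list alone). Their medians were 0.137 and -0.188 (camera adjusted p = 0.142 and 0.206, and adjusted p = 0.748 for both with an estimated correlation). With imeglimin there, tuft cell markers had 1 of 16 lower (0 adjusted over the list alone, median -0.0172, camera adjusted p = 0.692, and adjusted p = 0.969 with an estimated correlation), and without imeglimin 3 their median was above 0. In middle small intestine with metformin, stem cell markers had 0 of 14 called by edgeR (0 adjusted over the list alone). Their median was -0.249 (camera adjusted p = 0.000666, and adjusted p = 0.707 with an estimated correlation), -0.165 without control 1 and -0.133 without metformin 3 (camera adjusted p = 0.0657). Endothelial markers and neuron and glia markers each had 0 of 17 called (0 and 0 adjusted over the list alone). Their medians were -0.237 and -0.266 (camera adjusted p = 0.0151 and 0.00446, and adjusted p = 0.707 and 0.671 with an estimated correlation). The endothelial camera adjusted p was 0.0571 without control 1 and 0.0892 without metformin 1, and the other 0.115 without metformin 2. Erythrocyte markers had 0 of 5 called (2 lower adjusted over the list alone, median -0.542, camera adjusted p = 0.0154, and adjusted p = 0.707 with an estimated correlation). Their camera adjusted p was 0.123 to 0.2 without control 2 or 3 (medians -0.339 and -0.352) or metformin 2 or 3. With imeglimin there, enteroendocrine markers had 0 of 21 called (2 higher adjusted over the list alone, median 0.185, camera adjusted p = 0.0207, and adjusted p = 0.739 with an estimated correlation). Without control 2 their median was 0.107 (camera adjusted p = 0.0822), and without control 3 it was 0.316. In proximal small intestine with imeglimin, erythrocyte markers had 0 of 5 called (4 lower adjusted over the list alone, median -0.699, camera adjusted p = 0.000145, and adjusted p = 0.206 with an estimated correlation). In distal small intestine neuron and glia markers had 0 of 18 called with either drug (0 and 0 adjusted over the list alone). Their medians were -0.621 with metformin and -0.543 with imeglimin (camera adjusted p = 2.69e-05 and 2.44e-05, and adjusted p = 0.471 and 0.556 with an estimated correlation). Tuft cell markers had 0 of 15 called there with metformin (0 adjusted over the list alone, median -0.45, camera adjusted p = 0.00394, and adjusted p = 0.471 with an estimated correlation). The liver, pancreatic and other lists named without values had no camera call with all libraries.

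The effect of each drug was then compared between the 4 chronic segments, over tables counted separately. For metformin 809 of 20053 genes had an effect that differed between segments, 457 with the replicate block, 313 without replicate 1, 89 without replicate 2 and 73 without replicate 3. Mthfd2 stood at -0.49, -0.75, 0.86 and 2.98 in proximal, middle and distal small intestine and colon (edgeR adjusted p = 7.6e-07), and Atf5 at -0.47, -0.44, 1.29 and 2.35 (edgeR adjusted p = 4.37e-06). For imeglimin 594 differed, 277 with the replicate block, 58 without replicate 1, 7 without replicate 2 and 6 without replicate 3. Hkdc1 stood at 0.14, 0.02, 0.22 and 3.15 (edgeR adjusted p = 2.07e-07), and Tfrc at 0.00, 0.19, -0.15 and 2.65 (edgeR adjusted p = 5.49e-06).

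Acute and chronic effects in colon differed in 1205 of 19369 genes for metformin, 246 without replicate 1, 495 without replicate 2 and 48 without replicate 3. For imeglimin they differed in 3154, 1950 without replicate 1, 605 without replicate 2 and 993 without replicate 3. Dose, route and time differed together between these experiments. The content of the colon samples differed as well. Ileum regional genes had a mean log2 CPM of 5.54 to 5.85 in the acute controls (14 genes). In the chronic controls it was 2.35 to 2.66 (13 genes). None of these differences can be told apart in the interaction. Ces2e stood at 0.09 in acute and 1.85 in chronic colon with metformin (edgeR adjusted p = 4.4e-05). With imeglimin Gdf15 stood at 6.67 and 0.51 and Areg at 5.5 and 0.11 (both edgeR adjusted p = 1.51e-06), and Tfrc at 0.41 and 2.65 (edgeR adjusted p = 3.4e-06).

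The fold changes of metformin and imeglimin against the same controls were correlated across genes, which are not independent replicates. In acute colon r was 0.764, against 0.496 in simulations of unchanged groups that shared controls, and the covariance 0.318 against 0.0534. In chronic colon r was 0.70 against 0.504, and the covariance 0.297 against 0.0663. In proximal, middle and distal small intestine r was 0.499, 0.457 and 0.57 against 0.497, 0.501 and 0.49, with covariances of 0.102, 0.107 and 0.199 against 0.0476, 0.0768 and 0.112. Without the filter on low counts r was 0.588 in acute and 0.597 in chronic colon and 0.498, 0.476 and 0.511 in proximal, middle and distal small intestine, and with the replicate block it was 0.509 in middle small intestine. The simulations were not repeated with these settings. In acute colon 1788 genes were higher and 1217 lower with both drugs, against 376 and 232 for independent lists, and 0 were opposite. In chronic colon 1074 were higher and 508 lower with both, against 173 and 76.1, and 3 were opposite. The simulated overlap was at most 1 gene. With 3 controls, no split leaves at least 2 libraries on each side, so part of the excess may come from the shared controls.

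Single-cell counts of colon after 12 weeks held 8000, 4730 and 12928 cells in the matrices named CT, Ime and Met, with median UMIs of 2342, 1355 and 5496 per cell. With 1 matrix per name there was no test. Goblet-like cells, held in clusters 7 to 10 in every matrix, made up 20.04% (95% interval 19.2 to 20.9), 21.2% (20.05 to 22.4) and 21.8% (21.1 to 22.5). These shares depended on the setting, and Met went from the highest to the lowest under every other one. With at least 500 detected genes they were 16.3%, 18.97% and 12.8%, and at Leiden 0.5 they were 19.05%, 20.2% and 14.5%. Without the cells of highest doublet scores, a setting chosen after the data were seen, they were 15.8%, 17.2% and 12.3%. Colonocyte-like cells made up 8.59% (7.98 to 9.22), 5.77% (5.12 to 6.48) and 27.6% (26.8 to 28.3), while 18.4%, 16.3% and 0.82% of cells were in no named class. Their shares were 21.8%, 14.6% and 28.7% with at least 500 detected genes, 24.9%, 20.99% and 23.7% at Leiden 0.5, and 25.8%, 21.7% and 27.96% without the highest doublet scores. Stem and transit amplifying-like cells of Met, the lowest of the 3 at 6.34%, were the highest at Leiden 0.5 (11.2%, 14.2% and 19.2%) and with at least 500 detected genes (3.49%, 5.11% and 5.87%). Enteroendocrine-like cells made up 2.05% (1.75 to 2.39), 2.43% (2.01 to 2.91) and 1.199% (1.02 to 1.40), and no cluster was named so at Leiden 0.5. Cluster 7, of 1073 cells with a low UMI count, was 87.9% Met, 7.2% CT and 4.9% Ime, and held the largest number of the goblet-like cells of Met, while cluster 8 held that of CT and of Ime. Summed over goblet-like cells, Ces2e stood at 44.3 CPM (Poisson 95% interval 41.3 to 47.4) in CT, 81.5 (74.1 to 89.4) in Ime and 143 (141 to 146) in Met. In fibroblast-like cells, given as background because Ces2e is an epithelial gene, it stood at 4.88, 4.25 and 31.0 CPM.

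**Figure D4:**
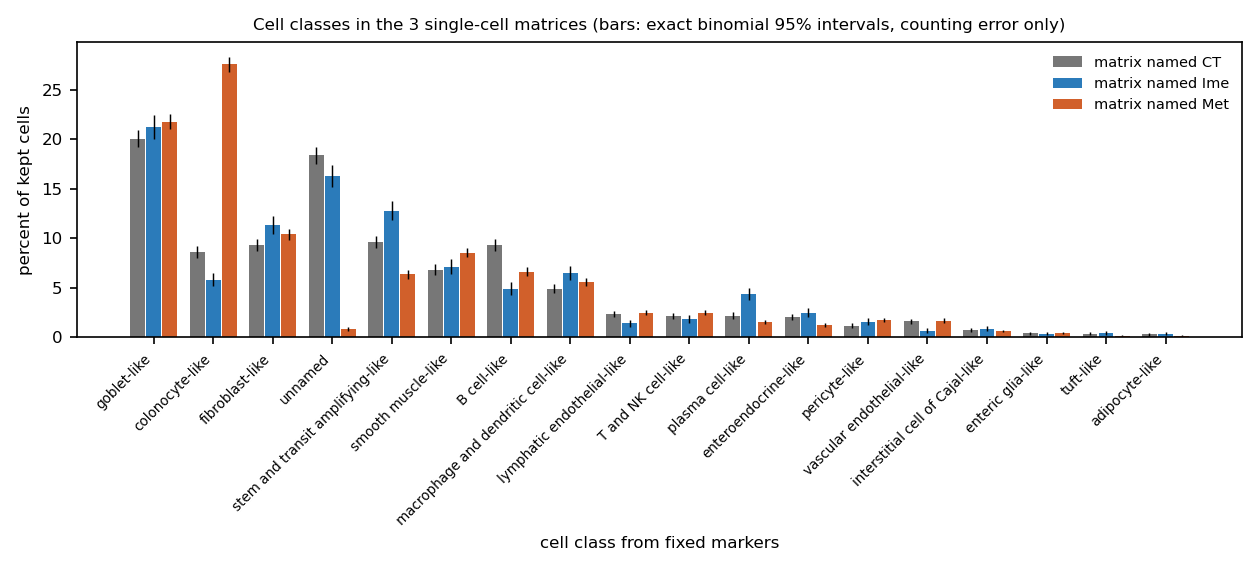
Bars give the share of cells (y axis, percent) in each named class for the matrices named CT, Ime and Met, with exact 95% binomial intervals that cover counting error only. Goblet-like cells lie between 20.04% and 21.8% in the 3 matrices with the setting drawn, while Met lies lowest, at 12.3% to 14.5%, with the 3 other settings. Colonocyte-like cells of CT stand at 8.59% as drawn and at 21.8% to 25.8% with the other settings, and median depths differ between 1355 and 5496 UMIs.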

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

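The tests of pancreatic tissue, lymphoid tissue, library depth, a shift of the whole single-cell library and an epithelial difference, and all counts of other splits, were chosen only after the results were seen, and the thinning of the cells before.

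The effect of metformin differed between the 4 chronic segments in 809 genes by edgeR. For the 5 with the smallest p, the largest difference between any pair of segments was 2.41 for Dclre1a, 3.73 for Mthfd2, 1.10 for Stk40, 2.82 for Atf5 and 2.55 for Vldlr. The effect of imeglimin differed in 594 genes, with largest differences of 3.12 for Hkdc1, 2.80 for Tfrc, 3.29 for Rtn4r, 2.01 for Gstm3 and 1.57 for Mcm10. Rtn4r and Mcm10 missed the threshold without replicate 2 (edgeR adjusted p = 0.0659 for each) and Gstm3 and Mcm10 without replicate 3 (0.136 for each). If segments came from the same mice, these fits treat linked libraries as separate. Of 80 splits that reassigned labels, 5 gave as many genes for metformin (real 809, highest other 2920), which does not exclude chance, and 2 for imeglimin (real 594, highest other 879), a share under 0.05. The highest others swapped drug and control in the whole distal table, where by construction a common effect counts as a difference. Such a swap of a whole table was in 3 of the 4 other splits as large for metformin and in the 1 for imeglimin, and without it the highest other was 821 and 368. The number of splits was raised from an earlier 25 after the first counts were seen.

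The effect of metformin differed between acute and chronic colon in 1205 genes. Chronic minus acute was 1.76 for Ces2e, 2.76 for Dclre1a, 1.63 for Ces1d, 1.89 for Pm20d1 and 0.99 for Chdh. For imeglimin it differed in 3154 genes, by -6.16 for Gdf15, -5.39 for Areg, 2.24 for Tfrc, -2.06 for Jmjd6 and -1.80 for Rhou. Of 100 splits, 6 gave as many for metformin (real 1205, highest other 6519) and 5 for imeglimin (real 3154, highest other 6347), which does not exclude chance. The highest others swapped drug and control in the acute table, where by construction a common effect counts as a difference. Without a swap of a whole table the highest other was 2457 and 4124.

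For each comparison of 3 libraries with 3 there were 10 splits, too few for a share under 0.05. The real count and the highest other were 3607 and 1, 6085 and 0, and 118 and 3 in acute colon (metformin, imeglimin, and imeglimin against metformin), 710 and 0, 200 and 8, and 189 and 0 in proximal, 61 and 0, 5 and 0, and 0 and 1 in middle, and 114 and 1, 4 and 0, and 9 and 320 in distal small intestine, and 3669 and 1, 2433 and 1, and 114 and 30 in chronic colon. As many genes as in the real split came from 1 split in each, except 10 for imeglimin against metformin in middle and 2 in distal small intestine. By the batch tag, 4 of the 10 splits part every pair, as the real one does.

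Pancreatic transcripts appeared in the chronic colon table. In control 3 the acinar marker list had a mean log2 CPM of 10.4, which was 8.07 above the highest of the other libraries, with Cela2a at 3160 and Cpb1 at 1940 CPM. Of 8 members 5 were called lower with each drug, and 0 without control 3. Pancreatic tissue in that library is a candidate source. No biological explanation was tested.

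In distal small intestine a split that ignored treatment (imeglimin 1, metformin 2 and metformin 3 against the other three) gave 320 genes, which points to a structure of the samples. The sides had total counts in a ratio of 1.01, which argues against library depth. B and plasma cell markers differed between the sides by a median of 4.67 log2 units, with 18 of 19 on 1 side and the exception at -0.272. Lymphoid tissue in some libraries may account for the split, and because not every marker lay on 1 side this stays open.

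In the single-cell data, 97.31% of the colonocyte-like and stem-like cells of the matrix named Met, 4382 in number, lay in clusters that this matrix filled to 90% or more. After thinning to 1000 UMIs per cell, which left out 1865 cells of CT, 1818 of Ime and 1174 of Met, the share was 60.68%, so depth may account for a part of it. A shift that fills clusters in every cell type is argued against by the stromal and immune cells of Met. Of these 0% lay in such clusters before thinning and 1.63% after. Of the 2814 goblet-like cells of Met 0% lay in clusters that Met filled to 90% or more before thinning and 1.23% after. The goblet-like cluster 7, at 87.9% Met, and the smooth muscle-like cluster 29, at 85.7%, came close to that limit before thinning. Ces2e also stood higher in fibroblast-like cells of Met, so a weaker shift of the whole library stays open. A difference limited to the colonocyte-like and stem-like cells, such as dissociation, and the treatment the matrix is named for cannot be told apart with 1 matrix per name.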

How the results depend on the processing

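The covariates, the excluded pair of libraries, the doublet score limit and the list tests without single libraries were chosen only after the data were seen. The alternative without called doublets was not run, since the caller marked 0. The cause of the moves below was not tested. RLE scaling in the edgeR fit left all 19 counts of genes within 1.5 times. Of the results on named genes, called or not, 503 kept their side of the threshold with the replicate block and 76 missed it. Over the left-out libraries 2659 kept it, 746 missed it and 9 newly passed. Of called genes, 51 of 60 and 57 of 63 held without each library in turn for metformin and imeglimin in acute colon. In chronic colon 54 of 69 and 45 of 61 did. Between the drugs 0 of 15 did in acute and 3 of 19 in chronic colon, and 0 of 16 in proximal small intestine. With the estimated correlation 257 of 687 list results missed the threshold, and 430 kept their side of it, including results that had not passed before. Of the 5 correlations of the drugs' effects across genes, 4 moved without the filter on low counts and 1 with the replicate block. Of the single-cell shares 27 of 48 moved with at least 500 detected genes, 20 of 45 at Leiden 0.5 and 14 of 54 without the highest doublet scores. Of the single-cell levels 145, 136 and 163 moved, in the same order. Depth limits the precision for genes of low counts and for levels in single cells.

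With the replicate block, the number of genes was 19 for imeglimin against metformin in acute colon, 470, 80 and 94 for metformin, imeglimin and the drugs against each other in proximal small intestine, 23 for metformin in middle, 17, 1 and 3 in distal small intestine, and 457 and 277 for the effects by region of metformin and imeglimin. The block moved no other count by over 1.5 times. It changed the call of 30 list results, 27 of which newly passed and 3 missed the threshold.

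The DESeq2 test gave 733 and 1292 for imeglimin against metformin in acute and chronic colon, 1527, 819 and 819 in proximal (in the order above), 475, 940 and 312 in middle and 960, 274 and 222 in distal small intestine, 1490 and 1281 by region, and 1820 for metformin in acute against chronic colon. Without the filter on low counts the number was 74 and 62 for the drugs against each other in acute and chronic colon, 74 for metformin in distal small intestine and 381 for imeglimin by region. With only the 2 groups compared it was 28 and 17 for the drugs against each other in acute and chronic colon, 30 for imeglimin and 392 for the drugs against each other in proximal, 10 for metformin in middle and 16, 2 and 0 in distal small intestine.

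With the smooth muscle marker score as covariate the number was 329 for the drugs against each other in acute colon, 4, 43 and 2 in proximal, 27 for metformin and 1 for imeglimin in middle, 1 and 1 in distal small intestine, and 111, 1308 and 0 in chronic colon. Ighv1-63 (metformin, 0.98) and Abcc2 (imeglimin against metformin, 0.12) turned their direction in proximal small intestine. With the B and plasma cell marker score it was 14 for the drugs against each other in acute colon, 0, 2 and 0 in proximal, 139 and 79 in middle, 184 and 10 in distal small intestine, and 658, 1301 and 5 in chronic colon, and H2-Eb1 (metformin, proximal, 0.0093) turned. Excluding control 1 and metformin 3 gave 6 for metformin and 11 for imeglimin in middle.

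Leaving out each library in turn gave 2169 to 3144, 4004 to 5935 and 0 to 156 in acute colon (in the order above), 52 to 493, 9 to 196 and 0 to 140 in proximal, 2 to 97, 1 to 8 and 0 to 2 in middle, 8 to 123, 1 to 2 and 0 to 12 in distal small intestine, and 2066 to 3429, 932 to 1623 and 11 to 543 in chronic colon. Without a whole replicate number, the interactions by region gave 73 to 313 for metformin and 6 to 58 for imeglimin. Those of acute against chronic colon gave 48 to 495 and 605 to 1950.

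Leaving out single libraries turned the camera direction of 16 list results, named here with the library and the range of the adjusted p over all left-out libraries. In acute colon, for the drugs against each other, they were the stress response (imeglimin 2, 3.87e-06 to 0.898), smooth muscle (metformin 2, 2.44e-08 to 0.378, and 0.367 without it) and neuron and glia markers (metformin 2, 1.02e-05 to 0.943). In middle small intestine they were mitochondrially encoded genes (control 1, 0.000643 to 0.43 with metformin and 0.00139 to 0.774 with imeglimin), smooth muscle (metformin, control 3, 0.00361 to 0.93, and 0.0155 without it), interferon response (imeglimin, imeglimin 1, 0.000426 to 0.849) and B and plasma cells (drugs against each other, metformin 3, 0.00408 to 0.857). In distal small intestine control 1 turned enterocyte markers (6.89e-05 to 0.685 with metformin and 0.00016 to 0.254 with imeglimin, and 0.24 without it), proliferation (imeglimin, 0.0145 to 0.765) and ileum genes (imeglimin, 0.00016 to 0.787). There imeglimin 2 turned fatty acid oxidation (imeglimin, 0.0401 to 0.893) and metformin 3 cholesterol synthesis (metformin, 0.0217 to 0.835). In chronic colon they were pancreatic markers (metformin, control 3, 0.0336 to 0.701) and interferon response (imeglimin, imeglimin 3, 0.000963 to 0.665). Of the other list results without 1 library, 3661 kept their side of the threshold, 220 missed it and 225 newly passed.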

Other observations

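The test of lysosomal genes and the list tests without single libraries were chosen only after the results were seen.

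Among targets of NRF2, the regulator of antioxidant genes, more members were called higher than lower in chronic colon with both drugs. With metformin 14 members rose and 1 fell, and with imeglimin 11 and 1 (14 and 2, and 13 and 2, adjusted over the list alone). Their medians were 0.48 and 0.45 (camera adjusted p = 9.63e-12 and 1.78e-08, and adjusted p = 0.157 and 0.237 with an estimated correlation). The ferritin light chain Ftl1 rose by 1.48 ± 0.096 with metformin (edgeR adjusted p = 7.17e-05), higher in all 3 libraries. In distal small intestine Paneth cell markers had 0 members called by edgeR over all genes with metformin and 15 lower adjusted over the list alone (median -1.49, camera adjusted p = 2.71e-16, and adjusted p = 0.471 with an estimated correlation). Their mean log2 CPM was 10.3 in control 1 against 8.91 and 8.55 in the other controls, and without control 1 the median was -0.79. Adipocyte markers in middle small intestine with metformin had 0 called over all genes and 9 higher adjusted over the list alone (median 1.78, camera adjusted p = 6.25e-14, and adjusted p = 0.671 with an estimated correlation). Their mean log2 CPM was 0.407 in control 1 against 2.67 and 2.90 in the other controls, and without control 1 the median was 1.19.

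A rise of lysosomal genes with metformin in small intestine was examined as a hypothesis with a list of lysosomal genes and targets of TFEB. In proximal, middle and distal small intestine 13, 10 and 7 members were called higher by edgeR and 0 lower, among 48, 49 and 49, with Tpp1, Ctsz and Fnip2 in all 3 segments. The medians were 0.19, 0.27 and 0.32 (camera adjusted p = 1.2e-13, 9.56e-31 and 5.77e-18). With an estimated correlation the adjusted p was 0.123, 0.0694 and 0.121, so the bound set for the hypothesis to fail was met. That bound was wrong, since a p over a threshold excludes nothing, and metformin may raise these genes, which stays open. In chronic colon 30 of 49 members were higher and 1 lower with metformin (median 0.33, camera adjusted p = 1.43e-13, and adjusted p = 0.128 with an estimated correlation). With imeglimin 1, 0, 0 and 14 members were called higher by edgeR in proximal, middle and distal small intestine and colon. The medians were 0.074, 0.118, 0.298 and 0.122 (camera adjusted p = 0.00652, 5.33e-06, 2.13e-14 and 0.000346, and adjusted p = 0.611, 0.686, 0.381 and 0.398 with an estimated correlation).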
